A study of Mus musculus with 21 samples.

How the data were processed

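Polyadenylated RNA from 21 libraries of mouse cells was sequenced after preparation from 1 µg of RNA with a poly-A kit and selection of fragments of 250 to 300 bp, per the labels. The libraries fell into 7 groups, with 3 each of MEF, C6FAE, C6F(L), C6F5UE-C6F(L)V and NSF-CiHeps, 4 of C6FAE-C6F(L) and 2 of pHeps. Groups and replicate numbers were taken from the labels. Nothing in the labels says whether the libraries of a group came from separate cultures or animals, so the spread between them can be smaller than the spread between independent experiments. The labels also give no day of collection for the induced cells.

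The deposited count tables hold raw counts per gene, without normalisation, for 54532 genes each. The authors aligned the reads with HISAT2 to GRCm38 (mm10), per the labels. The counting tool, its strand setting and the annotation release are not given in the sources used here. One count table holds NSF-CiHeps, another holds MEF, C6FAE, C6F(L) and C6FAE-C6F(L), and the remaining table holds C6F5UE-C6F(L)V and pHeps. The deposited FPKM tables (fragment counts scaled by gene length and library depth) served only to check the columns. Of 16 FPKM columns, 13 matched the count column of the same label and 3, all of MEF, matched the count column of another MEF replicate, which changes no group. One deposited table named as FPKM was identical to the count table of the same 5 libraries, and 1 FPKM cell was blank. Of the genes, 54409 were found in GENCODE release 21 for mouse, and 98.33% of these had the same coordinates there. Coordinates are those of the deposited tables, on GRCm38.

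Total counts per library ran from 9.18 M to 12.32 M. A count of 0 over a group was set to a floor of 3 counts over the group's total, so that a fold against it is a lower bound. Where a group held 1 to 3 counts, the ratio of count shares is given with its exact 95% interval. The same holds where leaving out a library brought a group to so few counts, and leaving out a library of a group at 0 counts lowers the bound by itself. Fitted fold changes against such groups depend on the prior count and are no bounds. Reads carry no molecular identifiers, so floors and intervals cover counting error only. Expression levels are CPM (counts scaled to a common library total) with scaling by trimmed mean of M values (TMM) over all 21 libraries, given as mean ± SD between libraries.

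Differences were tested on counts with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter (minimum count 10, minimum total 15) and the quasi-likelihood F test. Comparisons within the table of MEF and the first protocol used its 13 libraries and 16535 genes. The comparison of C6F5UE-C6F(L)V with pHeps used 5 libraries and 15531 genes. Comparisons across tables used all 21 libraries and 18605 genes, and in these the table and the group cannot be told apart. A gene was called when its Benjamini-Hochberg adjusted p was below 0.05 and its log2 fold change was at least 1 in size. The interaction was the log2 change from C6FAE to C6FAE-C6F(L) minus the change from MEF to C6F(L). The other tool was DESeq2 1.42.0 with its Wald test. DESeq2 sets no adjusted p for genes with an outlying count or a low mean, which counts here as a lost call.

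Before the data were examined, 28 gene lists, the comparisons, the test, the thresholds, the alternatives and the rule for named genes were fixed. The lists were hepatocyte secreted proteins, hepatocyte metabolic enzymes, drug metabolism and bile transport, hepatic transcription factors, fetal liver and biliary progenitor, fibroblast and mesenchyme, epithelial junction and adhesion, extraembryonic endoderm, pluripotency, Wnt pathway targets, TGF-beta and contractile targets, cAMP response, retinoic acid response, glucocorticoid response, cell cycle, acute phase, interferon response, cholesterol synthesis, unfolded protein and amino acid stress, and markers of macrophage, endothelium, hepatic stellate cell, keratinocyte, neural crest and neuron, muscle, adipocyte, intestine and stomach, and erythroid cells. They were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and again with an estimated correlation, with adjustment over the lists of each comparison. Of 280 list tests, 131 were called with the preset correlation and 14 of these also with the estimated one. The 14 were Wnt targets in 5 comparisons, macrophage markers in 4, retinoic acid in C6FAE, and the fetal liver, epithelial, glucocorticoid and interferon lists in C6F(L), the last 4 against MEF. In 28 tests the list's median, mean and test direction differed in sign, and 0 of those were called. Counts of called list members were also taken with p adjusted over the list alone.

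Named genes were the 9 sentinels Alb, Afp, Hnf4a, Cdh1, Epcam, Sall4, Sox17, Col1a1 and Thy1, the 5 largest called rises and falls among genes with a mean of at least 10 CPM and no overlap between groups, leaving out predicted genes, and up to 3 called members of each list in its main direction with 1 in the other. Near-identical genes such as Krt6a and Krt6b or the Cyp3a, Ugt1a and Saa families share reads, so their values may hold counts of relatives. A position between MEF and pHeps was computed per library as the median, over genes called between those groups, of the log2 change from MEF divided by the whole change, without a test.

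The test was tested on simulated data with the libraries' own sizes and, for each gene, 1 spread shared by all libraries of the fit. The real spread was unequal. Between replicates, the chi-square per gene against counting noise was 3.31 to 4.39 in MEF, C6FAE and C6F(L). In C6FAE-C6F(L) it was 23.45 to 158.59. The simulation therefore cannot show how the test behaves with groups of such unequal spread. At a 3-fold change, 71.00% of changed genes were recovered for C6FAE against MEF and 52.53% for the interaction, and at 8-fold 93.00% and 81.05%. Between 4 and 11 unchanged genes were called per simulation, no changed gene was called in the wrong direction, and 0 of 27 random lists were called. Genes were drawn independently there, so the simulation cannot show how often lists of correlated genes are called falsely. Alternatives were DESeq2 size factors, library size only, the DESeq2 test, other low-count filters, other sets of libraries in the fit, other prior counts, the replicate number as a block and leaving out each library in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. FPKM values were not used in any comparison, because counts carry the depth that the test needs.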

Results

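RNA was sequenced from mouse fibroblasts, from cells made from them with small molecules, and from hepatocytes. MEF are mouse embryonic fibroblasts grown in serum. C6FAE are MEF treated with 20 µM CHIR99021 (a GSK3 inhibitor that activates Wnt signalling), 10 µM 616452 (a TGF-beta receptor inhibitor), 50 µM Forskolin (which raises cAMP), 0.05 µM AM580 (a retinoic acid receptor agonist) and 5 µM EPZ004777 (a DOT1L inhibitor) in medium with bFGF. C6F(L) are MEF in a hepatocyte medium with dexamethasone, HGF, EGF and FGF4, which held the first 3 compounds at the same doses for 4 days and then at 3, 2 and 2 µM. C6FAE-C6F(L) received C6FAE for 4 days and then C6F(L). C6F5UE-C6F(L)V received a mixture with 1 µM CH55 (another retinoic acid receptor agonist) and 0.05 µM UNC0638 (an inhibitor of the histone methyltransferases G9a and GLP) in place of AM580, and then C6F(L) with vitamin C. NSF-CiHeps were made the same way from neonatal skin fibroblasts, and pHeps are hepatocytes kept in culture for 2 days.

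Total counts per library were 11.63 M to 12.32 M in MEF, 11.43 M to 11.97 M in C6FAE, 10.7 M to 11.55 M in C6F(L) and 10.83 M to 11.41 M in C6FAE-C6F(L). They were 9.18 M to 11.16 M in C6F5UE-C6F(L)V, 11.48 M to 12.15 M in NSF-CiHeps and 10.52 M to 11.14 M in pHeps. The first principal component held 44.36% of the variance over 18605 genes and the second 18.37%. Ribosomal protein genes took 2.83% of counts in MEF, 5.64% in NSF-CiHeps, 5.84% to 7.25% in the groups made from MEF and 8.43% in pHeps (group means). Mitochondrial genes took 1.45% in MEF, 2.45% in C6FAE, 2.16% in C6F(L), 1.13% in C6FAE-C6F(L), 0.64% in C6F5UE-C6F(L)V, 2.49% in NSF-CiHeps and 0.8% in pHeps. C6FAE-C6F(L) replicate 4 stood apart, with 3.77% of counts in ribosomal protein genes against 7.8% to 9.54% in the other 3 libraries. Its values are given for some, not all, of the results that they move.

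**Figure D1:**
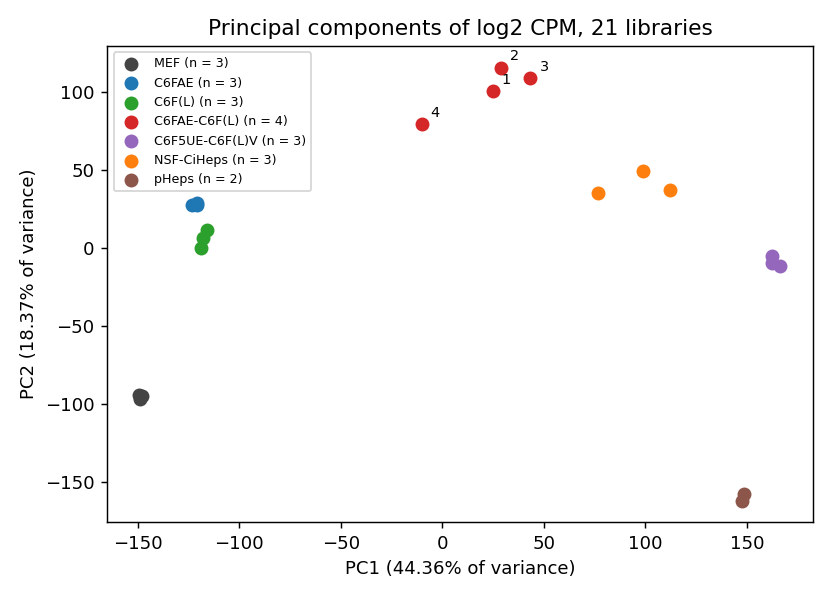
First and second principal components of log2 CPM over 18605 genes (x axis, 44.36% of variance; y axis, 18.37%), with 1 point per library coloured by group and the C6FAE-C6F(L) replicates numbered. MEF sit between -149.13 and -148.02 on the first component and C6F5UE-C6F(L)V between 162.28 and 166.54, while C6FAE-C6F(L) replicate 4 sits at -10.17 and the other 3 of its group between 24.85 and 43.45.

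The first question was what C6FAE alone did to MEF. Wnt targets rose, among them Sp5 (ENSMUSG00000075304, GRCm38 chromosome 2, 70474923 to 70477729), a Wnt-induced repressor that reached 83.6 ± 3.49 CPM (SD, n = 3) from 0 counts in MEF, at least 971-fold higher. Notum, a secreted Wnt inhibitor, rose to 249 CPM (log2 fold change 9.35, SE 0.34) and the transcription factor Tcf7 to 222 CPM (7.36, SE 0.26). Retinoic acid response genes rose with them, such as Cyp26a1, which degrades retinoic acid (8.22, SE 0.53), and Lrat, which esterifies retinol and reached 114 CPM from 1 count in MEF, a ratio of 3981 (95% interval 714 to 157273). Transcription factors of extraembryonic endoderm rose as well. Sox17 (ENSMUSG00000025902, chromosome 1, 4490931 to 4497354) reached 113 ± 7.24 CPM from 3 counts in MEF, a ratio of 1311 (448 to 6358), and Sall4 (ENSMUSG00000027547, chromosome 2, 168748332 to 168767943) reached 21.1 ± 1.81 CPM from 0 counts, at least 245-fold higher. All 3 counts of Sox17 in MEF lay in replicate 2 and the count of Lrat in the same library, and without it MEF held 0 counts of both and only lower bounds were left, at least 871-fold and 882-fold. By list, 14 of 16 tested Wnt targets rose and 1 (Lgr5, -2.87) fell (camera adjusted p = 2.7e-08), and 11 of 13 retinoic acid genes rose (camera adjusted p = 1.7e-05). Of 15 extraembryonic endoderm genes 11 rose and 1, Dab2, fell (camera adjusted p = 4.2e-04, and adjusted p = 0.168 with an estimated correlation).

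Epithelial genes rose and macrophage and interferon genes fell in the same libraries. Cdh1 (E-cadherin, ENSMUSG00000000303, chromosome 8, 106603351 to 106670246) rose from 0.721 ± 0.362 to 51.9 ± 1.33 CPM (log2 fold change 6.16, SE 0.34, adjusted p = 7.0e-08). Epcam rose to 43.9 CPM (7.91), with a ratio of 255 that was 508 (140.4 to 4198) over 2 counts without MEF replicate 2, and Ocln, a tight junction protein, rose from 0 counts by at least 230.2-fold. C1qa, a complement gene of macrophages (ENSMUSG00000036887, chromosome 4, 136895917 to 136898803), fell from 324 ± 44.1 CPM to 0 counts, at least 3913-fold, and the microglia and macrophage gene Fcrls fell from 384 CPM by at least 4642-fold. Oas1a, an interferon-induced antiviral enzyme, fell by 6.19 log2 units, with a ratio of 78.8 in favour of MEF that was 132 (36.3 to 1094) over 2 counts without C6FAE replicate 2. Of 25 epithelial genes 23 rose (camera adjusted p = 1.3e-12, and adjusted p = 0.0551 with an estimated correlation), and of 16 genes of fetal liver and biliary progenitors 11 rose and 2 fell (camera adjusted p = 0.00253, and adjusted p = 0.131 with an estimated correlation). All 11 macrophage genes fell (camera adjusted p = 1.6e-11). Of 15 interferon genes 14 fell (camera adjusted p = 7.5e-07, and adjusted p = 0.0622 with an estimated correlation), as did 6 of 14 genes of unfolded protein and amino acid stress, such as Chac1 (-3.97) and Trib3 (-3.97), with none higher (camera adjusted p = 4.7e-05, and adjusted p = 0.0551 with an estimated correlation).

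Fibroblast genes moved both ways under C6FAE. Lox, which crosslinks collagen, fell (log2 fold change -3.59), and the mesenchymal transcription factor Twist1 rose (2.41). Col1a1 (collagen I, ENSMUSG00000001506, chromosome 11, 94936224 to 94953042) went from 12494 ± 522 to 3693 ± 329 CPM (-1.75, SE 0.66, adjusted p = 0.04), a call that was lost without any 1 of the 6 libraries (adjusted p from 0.0706 to 0.107). The call was also lost with library size only (adjusted p = 0.0591) and with the DESeq2 test, which set no adjusted p. The SE rests on a spread shared by all 13 libraries of the fit. Among them was C6FAE-C6F(L) replicate 4, at 1172 CPM of Col1a1 against 189 ± 71.8 CPM in the rest of its group, which was not left out for this comparison. Thy1 was at 908 against 504 CPM, which did not pass (adjusted p = 0.0566). Of 26 fibroblast genes 5 rose and 13 fell (camera adjusted p = 0.278), and without C6FAE replicate 2 the number lower was 8. Among hepatocyte genes, Alb (albumin) was at 0.416 CPM and Hnf4a at 0.11 CPM, and neither these nor Afp passed (adjusted p = 0.235, 0.218 and 0.563). Of 19 hepatocyte secreted proteins 1 rose and 3 fell (camera adjusted p = 0.803), of 13 metabolic enzymes 3 rose and 1 fell (camera adjusted p = 0.678), and of 13 hepatic transcription factors 4 rose, among them Prox1 (5.85), and 2 fell (camera adjusted p = 0.195). The cell cycle genes Aurka (1.30) and Top2a (1.11) were among 3 of 25 that rose (camera adjusted p = 0.00157, and adjusted p = 0.574 with an estimated correlation). Of 6 adipocyte genes 5 fell (camera adjusted p = 0.00157, and adjusted p = 0.196 with an estimated correlation). Over all 16535 genes, 2583 were higher and 2438 lower. These list counts were the same when adjusted over the list alone, except for 6 fibroblast genes and 2 enzymes higher. With library size only, the median of all genes moved from 0.02 to 0.12, and the fold changes are relative to the TMM scaling.

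C6F(L) given to MEF directly was compared with MEF to see what the hepatocyte medium did without the C6FAE step. Glucocorticoid response genes rose, among them the transcription factor Zbtb16, which reached 112 ± 2.97 CPM (log2 fold change 7.10, SE 0.43), the chaperone Fkbp5, which rose from 20.9 to 381 CPM (4.19, SE 0.21), and the clock gene Per1 (2.08). The cAMP target Nr4a3 rose (2.39). TGF-beta targets fell, such as Ltbp2 (-4.92), Ctgf (-4.94) and the feedback repressor Skil (-2.97). Epithelial genes rose, with Cdh1 at 44.8 ± 3.8 CPM (5.94, SE 0.34), Epcam at 20 ± 4.5 CPM (6.77, a ratio of 116, and 231 with an interval of 63.6 to 1910.3 over 2 counts without MEF replicate 2) and the epithelial splicing factor Esrp1 at least 102.4-fold higher from 0 counts. All 13 glucocorticoid genes rose (camera adjusted p = 3.3e-10), as did 24 of 25 epithelial genes (camera adjusted p = 1.5e-17). Of 15 cAMP genes 11 rose and 1 fell (camera adjusted p = 1.6e-04, and adjusted p = 0.0747 with an estimated correlation), and of 17 TGF-beta genes 11 fell (camera adjusted p = 3.6e-05, and adjusted p = 0.235 with an estimated correlation). Of 16 Wnt targets 11 rose, among them the inhibitor Wif1 (5.95), and 1, the cyclin Ccnd1 (-2.61), fell (camera adjusted p = 2.4e-05). Of 16 fetal liver and biliary genes 12 rose and 1 fell (camera adjusted p = 3.6e-05).

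Macrophage and interferon genes fell under C6F(L) too. C1qa was left with 2 counts, a ratio of 5132 (1420.3 to 42380.4) in favour of MEF, and without C6F(L) replicate 3, which held both, it fell by at least 2242-fold. Fcrls fell by at least 4059-fold. All 11 macrophage genes (camera adjusted p = 4.2e-14) and 14 of 15 interferon genes fell (camera adjusted p = 5.6e-08). Keratinocyte genes varied between libraries, with Krt5, a keratin of basal keratinocytes (ENSMUSG00000061527, chromosome 15, 101707070 to 101712898), at 27.8 ± 33.1 CPM, at least 317-fold higher. Without C6F(L) replicate 1 the lower bound for Krt5 was 104.7-fold. Of 10 keratinocyte genes 8 rose (camera adjusted p = 6.5e-04, and adjusted p = 0.275 with an estimated correlation). Sox17 reached 19.2 ± 0.662 CPM, a ratio of 223 (76 to 1085), and without MEF replicate 2 it was at least 148-fold higher over 0 counts.

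Alb and Hnf4a were at or near 0 in C6F(L). Alb was at 1.56 ± 1.38 CPM against 1 count in MEF, a ratio of 54.9 (9.4 to 2209, adjusted p = 0.0305), a call lost without MEF replicate 1 (at least 12.4-fold over 0 counts, adjusted p = 0.0678), 2 (0.0807) or 3 (0.0805) or C6F(L) replicate 2 (a ratio of 29.6, 4.67 to 1233, adjusted p = 0.109). Hnf4a had 0 counts in both groups, and Sall4 and Afp did not pass (adjusted p = 0.591 and 0.407). Of 19 secreted proteins 6 rose (camera adjusted p = 0.0344, and adjusted p = 0.537 with an estimated correlation). Without MEF replicate 1, 2 or 3 or C6F(L) replicate 2 that count was 3, 2, 3 and 3. Of 9 acute phase genes 4 rose, among them Cp (ceruloplasmin, 3.23) (camera adjusted p = 0.00301, and adjusted p = 0.274 with an estimated correlation). Col1a1 at 8582 ± 521 CPM and Thy1 at 355 CPM did not pass (adjusted p = 0.528 and 0.267). Of 26 fibroblast genes 4 rose, such as Fbln1 (1.38), and 4 fell, such as Fap (-2.93) (camera adjusted p = 0.796), and the number higher was 2 without MEF replicate 2. Sult1d1, a sulfotransferase, rose from 0 counts by at least 637-fold. Over all genes 1755 were higher and 2047 lower. Adjusted over the list alone, 3 secreted proteins and 13 fetal liver genes were higher, 2 Wnt targets and 2 fetal liver genes were lower, and the other list counts were the same.

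C6FAE-C6F(L) against MEF tested the sequential treatment as a whole. Hepatocyte genes rose far above the floor. Alb (ENSMUSG00000029368, chromosome 5, 90460897 to 90476602) reached 361 ± 228 CPM (SD, n = 4) from 1 count in MEF, a ratio of 12867 (2309 to 508238, adjusted p = 1.0e-06). Replicate 4 was highest, at 629.9 CPM of Alb against 271.5 ± 172.2 CPM in the rest of its group. The hepatocyte transcription factor Hnf4a (ENSMUSG00000017950, chromosome 2, 163506808 to 163572910) reached 44.9 ± 20.9 CPM from 0 counts, at least 528-fold higher. Apolipoprotein Apoa1 reached 332 ± 311 CPM, at least 3860-fold higher, and alpha-fetoprotein, Afp, 44.3 ± 11.6 CPM (log2 fold change 8.47, SE 0.56). The tyrosine catabolism enzyme Tat rose by at least 53.8-fold to 4.62 CPM, while the histidine catabolism enzyme Hal (-2.01) and the lung and liver P450 Cyp2f2 (-4.94) fell. Without MEF replicate 1, which held its only count there, Alb was at least 2901-fold higher. The ratio of Afp was 389, and without MEF replicate 2 it was 1036 (186 to 40927) over 1 count, while the lower bound for Apoa1 was 2075-fold without C6FAE-C6F(L) replicate 1. All 19 tested secreted proteins rose (camera adjusted p = 2.5e-07, and adjusted p = 0.192 with an estimated correlation). Of 13 hepatic transcription factors 10 rose (camera adjusted p = 0.00154, and adjusted p = 0.174 with an estimated correlation), of 13 metabolic enzymes 8 rose and 1 fell (camera adjusted p = 0.038, and adjusted p = 0.285 with an estimated correlation), and of 14 drug metabolism and bile transport genes 10 rose and 2 fell (camera adjusted p = 0.0165, and adjusted p = 0.236 with an estimated correlation). Of 9 acute phase genes 8 rose (camera adjusted p = 0.0019, and adjusted p = 0.211 with an estimated correlation).

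**Figure D2:**
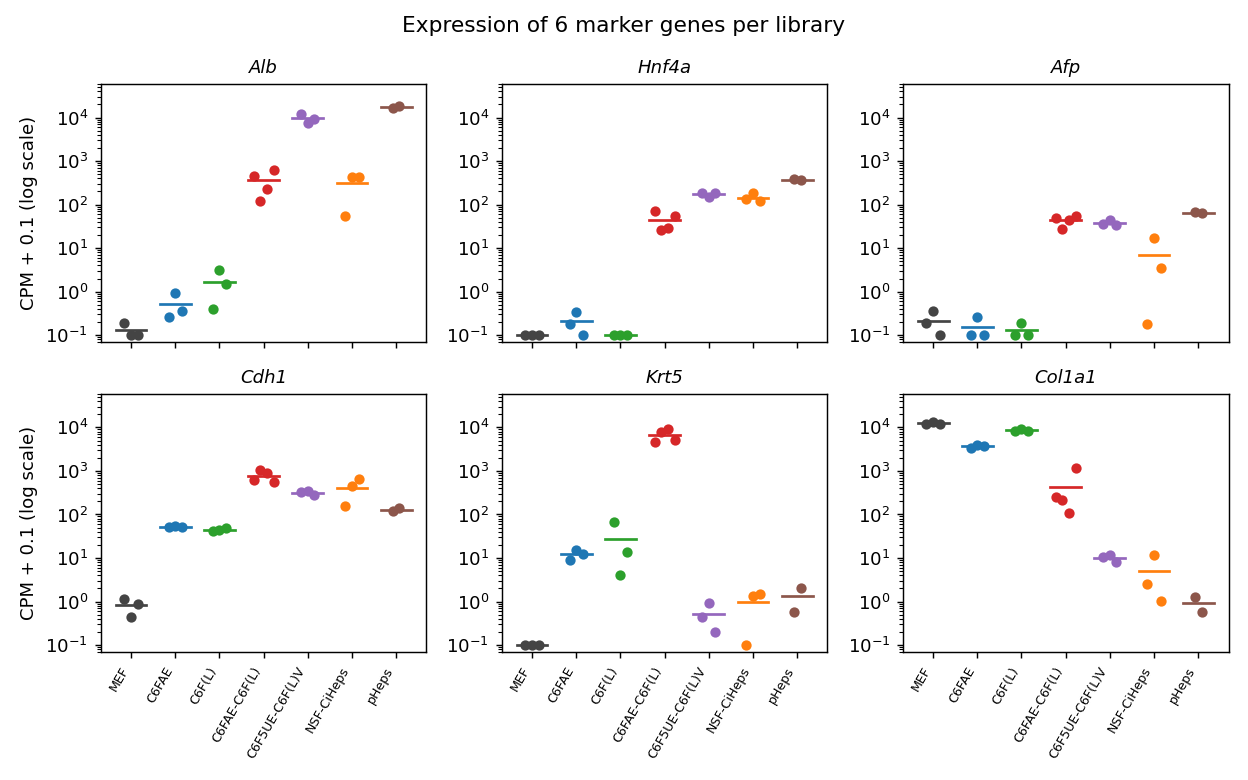
Expression of 6 marker genes in each of the 21 libraries as CPM + 0.1 on a log scale (y axis) by group (x axis), with 1 point per library, a line at the group mean and libraries with 0 counts drawn at 0.1. Alb rises from 1 count in MEF to 361 CPM in C6FAE-C6F(L), 9607 CPM in C6F5UE-C6F(L)V and 17414 CPM in pHeps, and Krt5 is at 6827 CPM in C6FAE-C6F(L) and at 27.8 CPM or less in every other group.

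Epithelial genes rose and fibroblast genes fell in C6FAE-C6F(L). Cdh1 rose to 770 ± 226 CPM (log2 fold change 10.06, SE 0.36, adjusted p = 2.3e-09), Epcam to 267 ± 138 CPM (10.52, a ratio of 1525, and 3043 with an interval of 842 to 25128 over 2 counts without MEF replicate 2), and Esrp1 by at least 1957-fold from 0 counts. Col1a1 fell to 435 ± 495 CPM (-4.84, SE 0.67, adjusted p = 5.5e-05, and -4.85 with no adjusted p, a lost call, with the DESeq2 test), the matrix protein Postn fell (-6.79), and so did Fap (-5.47) and Thy1 (-4.12). Replicate 4 held more of these transcripts than the other 3 libraries, and without it the log2 fold changes were -6.03 for Col1a1 and -7.76 for Postn. All 25 epithelial genes rose (camera adjusted p = 3.6e-17, and adjusted p = 0.0582 with an estimated correlation), 24 of 26 fibroblast genes fell (camera adjusted p = 9.2e-08, and adjusted p = 0.299 with an estimated correlation), and 15 of 17 TGF-beta and contractile genes fell (camera adjusted p = 3.0e-06, and adjusted p = 0.174 with an estimated correlation). Of 10 hepatic stellate cell genes 7 fell and 1 rose (camera adjusted p = 0.0196, and adjusted p = 0.22 with an estimated correlation). Of 11 macrophage genes 10 fell, C1qa by at least 4701-fold (camera adjusted p = 4.4e-09).

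Genes of other epithelia rose beside the hepatocyte genes. Krt5 was at 6827 ± 2241 CPM and Krt6a, a keratin of activated keratinocytes, at 2054 ± 418 CPM, both from 0 counts and at least 78596-fold and 23936-fold higher, and the desmosome gene Dsg3 rose by at least 8755-fold. Gkn1, a secreted protein of the stomach lining, reached 155 ± 140 CPM from 2 counts in MEF, a ratio of 2723 (754 to 22492), and villin, Vil1, 37.1 CPM, a ratio of 647 (179 to 5348). Both counts of Gkn1 and of Vil1 lay in MEF replicate 2, without which only lower bounds were left, at least 1207-fold and 287-fold, and the ratio of Gkn1 was 1580.1 (437 to 13053.5) without C6FAE-C6F(L) replicate 1. Of 10 keratinocyte genes 9 rose (camera adjusted p = 1.3e-05, and adjusted p = 0.192 with an estimated correlation), and all 8 genes of intestine and stomach rose (camera adjusted p = 1.7e-04, and adjusted p = 0.131 with an estimated correlation). Of 16 fetal liver and biliary genes 10 rose and 2 fell (camera adjusted p = 0.0019, and adjusted p = 0.174 with an estimated correlation), and of 15 extraembryonic endoderm genes 10 rose and 2 fell (camera adjusted p = 0.0081, and adjusted p = 0.22 with an estimated correlation). Sox17 was at 31.5 ± 18.7 CPM, a ratio of 369 (126 to 1791), and without MEF replicate 2 it was higher by at least 245-fold over 0 counts. Sall4 was at 0.933 ± 0.944 CPM, at least 11.2-fold higher (adjusted p = 0.0094), with a lower bound of 6.87-fold without replicate 4. Of 13 glucocorticoid genes 10 rose, Fkbp5 by 4.54 (camera adjusted p = 7.2e-05, and adjusted p = 0.174 with an estimated correlation), of 16 Wnt targets 10 rose and 2 fell (camera adjusted p = 0.00879, and adjusted p = 0.174 with an estimated correlation), and 2 of 3 pluripotency genes and the 1 tested erythroid gene were higher (camera adjusted p = 0.0621 and 0.603). Over all genes 3004 were higher and 3186 lower. Without replicate 4 there were 3135 and 3537, and 96.45% of the calls were kept. The list counts given for this comparison were the same when adjusted over the list alone.

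**Figure D3:**
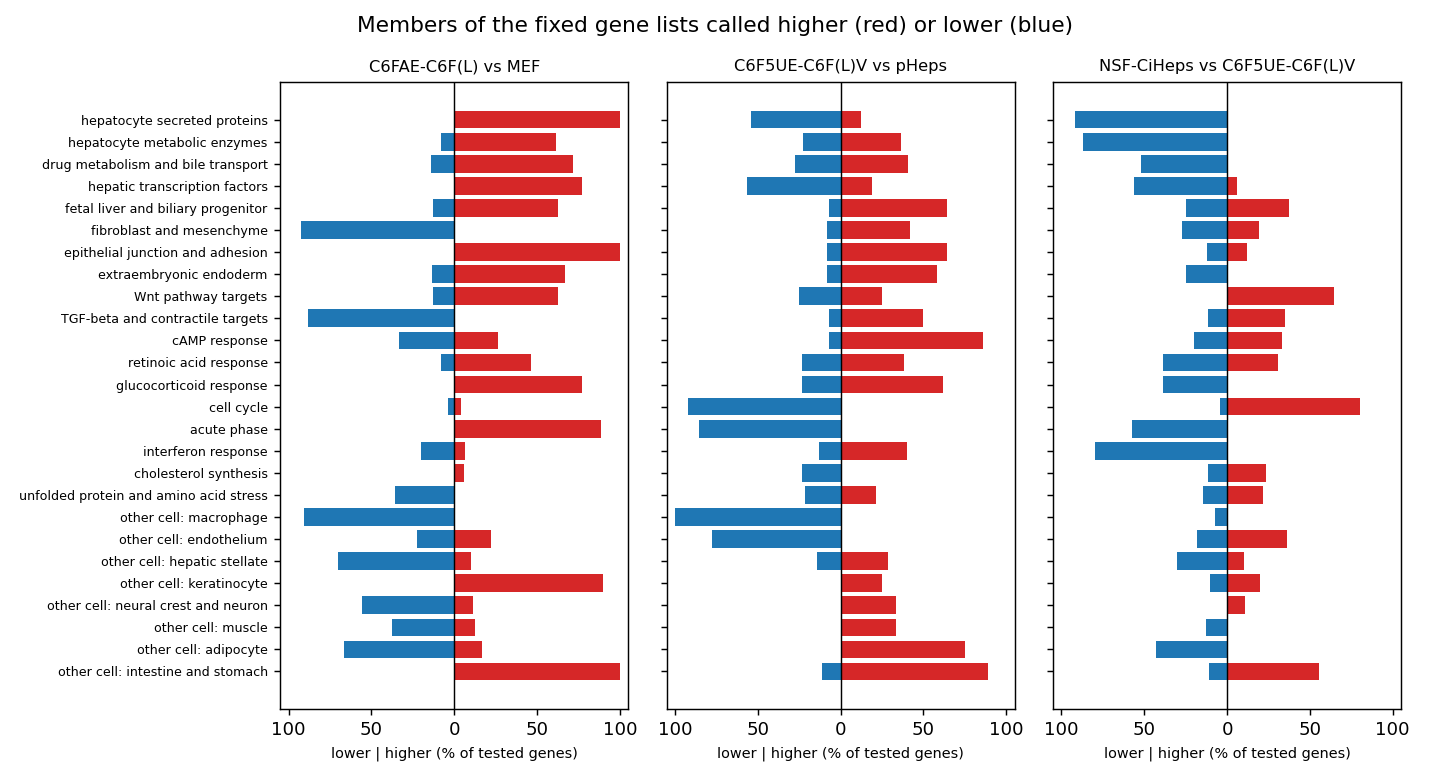
Share of the tested genes of each of 26 fixed lists called higher (red, to the right) or lower (blue, to the left), in % (x axis), for 3 comparisons (panels). All secreted protein, epithelial and intestine and stomach genes are higher in C6FAE-C6F(L) than in MEF, 23 of 25 cell cycle genes are lower in C6F5UE-C6F(L)V than in pHeps, and 20 of 25 are higher in NSF-CiHeps than in C6F5UE-C6F(L)V.

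Against C6FAE, its first step, C6FAE-C6F(L) showed the change that came with the second step. The labels give no length of treatment for C6FAE, so time in culture cannot be told apart from that step. Alb rose (log2 fold change 9.74, SE 0.86, and 10.70 without C6FAE replicate 2), the fibrinogen chain Fga rose from 0 counts by at least 527-fold, and Hnf4a rose (8.54, SE 0.71, a ratio of 413, and 1106 with an interval of 198 to 43691 over 1 count without C6FAE replicate 2). Afp rose from 2 counts, a ratio of 812 (224.5 to 6709), and without C6FAE replicate 2, which held both counts, by at least 363-fold. The urea cycle enzyme Arg1 rose (6.45, SE 0.81), and the P450 Cyp3a11 reached 3.22 CPM, at least 39.4-fold higher. C6FAE-C6F(L) replicate 4 was lowest in Arg1, at 42 CPM against 570.1 ± 54.24 CPM in the rest of its group. For Fga the lower bound was 333-fold without C6FAE-C6F(L) replicate 1. Wnt and retinoic acid genes fell, such as Tcf7 (-5.85), the Wnt feedback gene Nkd1 (-5.83) and Lrat (-9.03). Extraembryonic endoderm genes went both ways, and those that fell included Sall4 (-4.45, SE 0.69, and -5.13 without replicate 4), Sox17 (-1.84), Sox7 (-2.57) and Cited1 (35.5 to 4.41 CPM). Of 19 secreted proteins 18 rose (camera adjusted p = 1.1e-07, and adjusted p = 0.206 with an estimated correlation), and so did 12 of 14 drug metabolism genes (camera adjusted p = 1.5e-04, and adjusted p = 0.158 with an estimated correlation). Of 13 hepatic transcription factors 8 rose and 3 fell (camera adjusted p = 0.0347, and adjusted p = 0.248 with an estimated correlation). Of 16 Wnt targets 13 fell (camera adjusted p = 1.1e-06), and 8 of 13 retinoic acid genes fell (camera adjusted p = 6.3e-04, and adjusted p = 0.0814 with an estimated correlation). Of 15 extraembryonic endoderm genes 4 rose and 6 fell (camera adjusted p = 0.422).

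Epithelial, interferon and keratinocyte genes also rose over C6FAE. Cdh1 rose (log2 fold change 3.90), Epcam (2.61), Krt5 (9.13, SE 1.03) and the interferon regulator Irf7 (5.08, SE 0.75). Col1a1 fell (-3.08, SE 0.62, and -4.28 without replicate 4), as did Thy1 (-4.97) and the mesenchymal receptor Pdgfra (-4.24). Of 25 epithelial genes 24 rose (camera adjusted p = 2.1e-10, and adjusted p = 0.149 with an estimated correlation), of 15 interferon genes 13 rose (camera adjusted p = 6.8e-05, and adjusted p = 0.158 with an estimated correlation), and of 10 keratinocyte genes 8 rose (camera adjusted p = 6.8e-05, and adjusted p = 0.208 with an estimated correlation). Fibroblast genes fell, 20 of 26 (camera adjusted p = 2.0e-06, and adjusted p = 0.369 with an estimated correlation). Over all genes 2669 were higher and 2904 lower. Without replicate 4 there were 2685 and 3223. When adjusted over the list alone, 10 transcription factors were higher and the other list counts were the same.

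Against C6F(L), the same hepatocyte medium without the first step, C6FAE-C6F(L) held more hepatocyte and epithelial RNA. Alb was higher (log2 fold change 7.84, SE 0.75, and 8.70 without C6F(L) replicate 2), Hnf4a by at least 481-fold over 0 counts, the fibrinogen chain Fgg by at least 265-fold and Arg1 by 10.27 log2 units (SE 1.06). Afp was at a ratio of 1420 (254.6 to 56113) over 1 count, and at least 316-fold higher without C6F(L) replicate 2, which held it. Cdh1 (4.12), Epcam (3.75) and the desmosome gene Dsp (5.50) were higher, and Col1a1 (-4.29, SE 0.65, and -5.50 without replicate 4), Thy1 (-3.61) and the cAMP target Nr4a1 (-4.67) were lower. The stomach genes Pgc (pepsinogen C) and Gkn1 were higher by at least 4425-fold and 1655-fold over 0 counts, and Krt5 by 7.95 log2 units (9.56 without C6F(L) replicate 1). Without C6FAE-C6F(L) replicate 1 the lower bounds were 163.5-fold for Fgg, 2884-fold for Pgc and 960.3-fold for Gkn1. Sall4 was at a ratio of 30.6 (5.2 to 1236, adjusted p = 0.0219, and 18.8 without C6FAE-C6F(L) replicate 4), a call lost without C6F(L) replicate 1 (at least 6.903-fold over 0 counts, adjusted p = 0.0513), 2 (0.0735) or 3 (0.0752), and Sox17 did not pass (0.73, adjusted p = 0.11).

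By list, 16 of 19 secreted proteins were higher than in C6F(L) (camera adjusted p = 1.5e-06, and adjusted p = 0.312 with an estimated correlation), as were 8 of 13 hepatic transcription factors (camera adjusted p = 0.0042, and adjusted p = 0.296 with an estimated correlation), 22 of 25 epithelial genes (camera adjusted p = 3.1e-10, and adjusted p = 0.233 with an estimated correlation) and all 8 intestine and stomach genes (camera adjusted p = 1.1e-04, and adjusted p = 0.233 with an estimated correlation). Of 10 keratinocyte genes 8 were higher and 1 lower (camera adjusted p = 7.9e-04, and adjusted p = 0.374 with an estimated correlation). Of 26 fibroblast genes 23 were lower (camera adjusted p = 5.2e-09, and adjusted p = 0.374 with an estimated correlation), and of 15 cAMP genes 8 were lower and 1 higher (camera adjusted p = 0.00235, and adjusted p = 0.296 with an estimated correlation). Over all genes 2559 were higher and 2735 lower. Without replicate 4 there were 2666 and 3149. With p adjusted over the list alone, 17 secreted proteins were higher, 1 transcription factor was lower and the other list counts were the same.

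Whether C6F(L) acted differently on C6FAE cells than on MEF was tested with the interaction, the first change minus the second in log2 units. The Wnt targets Sp5 (83.6 to 2.25 CPM against 0 to 9.88 CPM) and Notum (difference -10.12, SE 0.39) went down in C6FAE cells and up in MEF. Sp5 had 0 counts in MEF, so its fitted difference of -15.00 depends on the prior count and is no bound, and with MEF at the floor the difference was -12.05 or lower. The same directions were seen for the retinoic acid target Cyp26a1 (131 to 1.01 CPM against 0.426 to 110 CPM, difference -14.96, SE 0.69, and -15.73 without C6FAE-C6F(L) replicate 1). The interferon genes Oas1a and Isg15 did the opposite, with Oas1a at 0.138 to 8.39 CPM against 10.9 to 0.221 CPM (difference 11.38, SE 0.53, and without C6FAE replicate 2, which left 2 counts in C6FAE, 12.29 from count shares, 10.42 to 15.34) and Isg15 at 9.37 (SE 0.60). Enzymes of cholesterol synthesis had positive differences, among them Sc5d, at 45.2 to 114 CPM against 88.8 to 44.4 CPM (2.34, SE 0.17). Twist1 went from 448 to 30.5 CPM after C6FAE and from 84.6 to 346 CPM after MEF (-5.90, SE 0.37), and Fbln1 (-4.59), Thy1 (-4.47) and Nr4a1 (-3.69) also had negative differences. In log2 units Cdh1 rose less from C6FAE (51.9 to 770 CPM) than from MEF (0.721 to 44.8 CPM, difference -2.04, SE 0.41). So did Epcam, at 43.9 to 267 CPM against 0.172 to 20 CPM (-4.16, SE 0.95, and without MEF replicate 2, which left 2 counts in MEF, -5.27 from count shares, -8.32 to -3.41). Both genes started near 0 in MEF and gained more CPM after C6FAE, so these differences do not show a weaker induction there. Sox17 and Afp were called with groups at 1 to 3 counts, at fitted differences of -9.46 and 10.96 (adjusted p = 6.4e-04 for Afp). From count shares they differed by -9.63 (-11.91 to -8.08) and 11.53 (6.34 to 20.20), where the ends of both counting intervals are combined. Sox17 was at -9.04 or lower without MEF replicate 2. Afp was at 10.37 or higher without C6FAE replicate 2, at 9.36 or higher without C6F(L) replicate 2 and at 10.12 (1.97 to 19.46) without MEF replicate 2. Col1a1 differed by -2.54 (SE 0.88, adjusted p = 0.0316, and -3.74 without C6FAE-C6F(L) replicate 4). Its call was lost without MEF replicate 1 (adjusted p = 0.0628), 2 (0.0613) or 3 (0.0655), C6FAE replicate 2 (0.0597) or 3 (0.0569), C6F(L) replicate 2 (0.056) or 3 (0.051), or C6FAE-C6F(L) replicate 1 (0.0525), and with the DESeq2 test, which set no adjusted p. Alb, Hnf4a and Sall4, with counts near 0 in C6F(L) or MEF, did not pass (adjusted p = 0.565, 1 and 0.241), while the DESeq2 test called them (adjusted p = 0.0372, 3.8e-05 and 0.0184).

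By list, the difference was negative for 13 of 16 Wnt targets and positive for 1 (camera adjusted p = 3.9e-08), and positive for 14 of 15 interferon genes (camera adjusted p = 5.1e-08, and adjusted p = 0.0769 with an estimated correlation), 16 of 17 cholesterol genes (camera adjusted p = 4.0e-05, and adjusted p = 0.336 with an estimated correlation) and 6 of 11 macrophage genes (camera adjusted p = 5.2e-10). The macrophage genes were at 7.78 CPM (Cd68) or less in C6FAE, with little room to fall, and their median change from C6FAE was 0.00, so that their median difference of 9.44 mirrors the median fall of 9.44 from MEF to C6F(L) and does not show that C6F(L) acted differently. It was positive for 8 of 19 secreted proteins (camera adjusted p = 8.4e-05, and adjusted p = 0.336 with an estimated correlation), 7 of 14 drug metabolism genes (camera adjusted p = 4.5e-04, and adjusted p = 0.153 with an estimated correlation) and 5 of 14 stress genes (camera adjusted p = 0.0033, and adjusted p = 0.153 with an estimated correlation). Of 26 fibroblast genes 15 had a negative and 2 a positive difference (camera adjusted p = 2.2e-04, and adjusted p = 0.576 with an estimated correlation), of 15 cAMP genes 11 and 2 (camera adjusted p = 0.00186, and adjusted p = 0.153 with an estimated correlation), of 13 retinoic acid genes 7 and 1 (camera adjusted p = 0.00312, and adjusted p = 0.0791 with an estimated correlation), and of 8 muscle genes 6 and 0 (camera adjusted p = 0.00191, and adjusted p = 0.153 with an estimated correlation). Over all genes 2677 were higher and 2782 lower, and without C6FAE-C6F(L) replicate 4 there were 2662 and 3188. There were 7 muscle genes lower when adjusted over the list alone, and the other list counts were the same. With the replicate number as a block, 23 fibroblast genes were lower, and with the DESeq2 test 14 secreted proteins and 11 macrophage genes were higher.

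C6F5UE-C6F(L)V were compared with pHeps, the hepatocytes of the same count table, to see how near the induced cells came. Albumin RNA was abundant in both, with Alb at 9607 ± 2155 CPM (n = 3) against 17414 ± 1073 CPM (n = 2), a log2 fold change of -0.86 (SE 0.13, adjusted p = 1.1e-04) that did not reach the 2-fold threshold, and -1.03, a call, without C6F5UE-C6F(L)V replicate 1. Afp was at 37.6 against 65.5 CPM (-0.80, not called), and Hnf4a was lower at 172 ± 18.9 against 375 ± 5.42 CPM (-1.13, SE 0.11), a call that was lost with library size only, where the change fell short of 2-fold. Secreted proteins were mostly lower, such as hemopexin, Hpx (-5.15), Ambp (-2.94) and coagulation factor F9 (-3.80), while Itih3 was higher (3.02). The P450 genes Cyp3a11, at 486 ± 125 CPM (4.69), and Cyp2b10 (5.58, and 6.16 without pHeps replicate 1) and the methyltransferase Bhmt (3.34) were higher, and the tryptophan enzyme Tdo2 was lower (-4.80). Of 24 secreted proteins 13 were lower and 3 higher (camera adjusted p = 0.0192, and adjusted p = 0.61 with an estimated correlation), and with all 21 libraries in the fit 7 were lower. Of 22 metabolic enzymes 8 were higher and 5 lower (camera adjusted p = 0.639), and of 22 drug metabolism genes 9 were higher and 6 lower (camera adjusted p = 0.583). Of 16 hepatic transcription factors 9 were lower, such as Foxa1 (-4.31) and Hhex (-2.04), and 3 higher (camera adjusted p = 0.124). Acute phase genes were lower, among them the iron hormone Hamp (-6.56) and Saa3 (-8.79), 12 of 14 in all (camera adjusted p = 5.6e-06, and adjusted p = 0.181 with an estimated correlation).

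Cell cycle, macrophage and endothelial genes were lower than in pHeps. Ccnb1 (-4.23) and Aurka (-3.90), which act in mitosis, were among 23 of 25 cell cycle genes lower (camera adjusted p = 3.0e-10, and adjusted p = 0.181 with an estimated correlation). The macrophage genes C1qb and Ccl6 fell to 0 counts from 278 and 527 CPM in pHeps, at least 2962-fold and 5611-fold lower, and all 14 macrophage genes were lower (camera adjusted p = 3.0e-10, and adjusted p = 0.181 with an estimated correlation). The endothelial cadherin Cdh5 was lower by at least 110.6-fold, and of 9 endothelial genes 7 were lower (camera adjusted p = 0.00127, and adjusted p = 0.181 with an estimated correlation). Biliary, stomach and fetal genes were higher, such as the keratins Krt7 (8.24) and Krt19 (6.82), the trefoil factor Tff3 at 3950 ± 195 against 6.46 CPM (9.25, SE 0.24), the stomach gene Gkn2 at 965 ± 181 CPM, at least 6775-fold higher, and Mucl3, at least 3123-fold higher. The imprinted fetal RNA H19 was at 1288 ± 268 CPM against 1 count, a ratio of 26581 (4770.4 to 1049900). Xist, the RNA of X inactivation and not a gene of these kinds, was at a ratio of 28582 (5129.6 to 1128952). The 1 count of H19 and of Xist lay in pHeps replicate 2, without which only the lower bounds of 4356-fold and 4684-fold were left. The Y-linked gene Ddx3y was at 4.51 against 60.3 CPM in pHeps. The sexes were thus not balanced between these groups, which cannot be told apart from their other differences.

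Of 25 epithelial genes 16 were higher than in pHeps, Cdh1 by 1.30 and Epcam by 4.27 (5.34 without pHeps replicate 1), and 2 lower, Cldn3 by 3.69 log2 units (camera adjusted p = 2.4e-04, and adjusted p = 0.181 with an estimated correlation). Of 14 fetal liver and biliary genes 9 were higher and 1 lower (camera adjusted p = 0.00127, and adjusted p = 0.181 with an estimated correlation), and of 9 intestine and stomach genes 8 were higher and 1 lower (camera adjusted p = 3.9e-04, and adjusted p = 0.181 with an estimated correlation). Of 14 cAMP genes 12 were higher, such as Fos (4.53) and Rgs2 (3.65), and 1 lower (camera adjusted p = 0.00381, and adjusted p = 0.44 with an estimated correlation). Of 24 fibroblast genes 10 were higher and 2 lower (camera adjusted p = 0.0309, and adjusted p = 0.434 with an estimated correlation), at low levels, with Col1a1 at 10.1 against 0.821 CPM (3.60, and 4.38 without pHeps replicate 1) and Thy1 at 3.35 CPM (2.01, adjusted p = 0.0129). The call on Thy1 was lost without pHeps replicate 2 (1.49, adjusted p = 0.0942) and with all 21 libraries in the fit (adjusted p = 0.0633), and its log2 fold change was 2.79 without pHeps replicate 1. Sox17 was at 16.2 ± 4.94 against 0.914 CPM (4.13), and of 12 extraembryonic endoderm genes 7 were higher and 1 lower (camera adjusted p = 0.00877, and adjusted p = 0.233 with an estimated correlation). Over 15531 genes 2864 were higher and 2276 lower. Adjusted over the list alone, 11 fibroblast and 8 endoderm genes were higher and the other list counts were the same. The 2 pHeps libraries give few degrees of freedom, and with library size only the median of all genes moved from 0.01 to 0.15.

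pHeps against MEF marked the ends of the conversion. Fibrinogen, Fgb, was at 5025 ± 325 CPM against 0 counts, at least 58388-fold higher, Apoa1 at least 31014-fold and the transcription factor Hnf4a at least 4352-fold. Alb had a ratio of 607059 (108954 to 23977604) over 1 count. Elastin, Eln, and the collagen Col8a1 were lower by at least 19680-fold and 10581-fold, and so were Col1a1 (-13.88, and -14.67 without pHeps replicate 1) and Thy1 (-9.25, and -10.04 without pHeps replicate 1). Cdh1 was higher (7.47, SE 0.52), as were Epcam (4.03, and 2.95 without pHeps replicate 1), Afp (9.02, a ratio of 569.8, and 1515 with an interval of 271.5 to 59898.5 over 1 count without MEF replicate 2) and the cell cycle kinase Cdk1 (2.67). Without MEF replicate 1 Alb was at least 136882-fold higher. Sox17 did not pass (adjusted p = 0.0741), but did without MEF replicate 2 (at least 7.04-fold over 0 counts, adjusted p = 0.0488), and Sall4 had 0 counts in both. All 24 secreted proteins (camera adjusted p = 6.9e-12), all 14 acute phase genes (camera adjusted p = 2.8e-08), 19 of 23 metabolic enzymes (camera adjusted p = 1.2e-06) and 15 of 16 hepatic transcription factors (camera adjusted p = 6.3e-07) were higher, each with adjusted p = 0.138 with an estimated correlation. Of 23 drug metabolism genes 20 were higher and 1 lower (camera adjusted p = 2.6e-06, and adjusted p = 0.138 with an estimated correlation), and 15 of 25 cell cycle genes were higher (camera adjusted p = 9.3e-06, and adjusted p = 0.306 with an estimated correlation). Fibroblast genes were lower, 25 of 26 (camera adjusted p = 4.9e-10, and adjusted p = 0.214 with an estimated correlation), and of 9 neural crest and neuron genes 6 were lower (camera adjusted p = 0.0534). Over 18605 genes 4536 were higher and 5057 lower, and the list counts adjusted over the list alone were the same. The groups come from different count tables, so that table and group cannot be told apart.

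On the scale set by these genes, C6F5UE-C6F(L)V lay nearest to pHeps. Their median position was 0.78 ± 0.021 (SD, n = 3) over the 4536 genes higher in pHeps and 0.84 ± 0.0256 over the 5057 lower ones, where MEF are 0 and pHeps 1. NSF-CiHeps lay at 0.44 ± 0.0824 and 0.64 ± 0.0376, and C6FAE-C6F(L) at 0.27 ± 0.0444 and 0.42 ± 0.0948 (n = 4), with replicate 4 lowest at 0.21 and 0.30. C6FAE lay at 0.15 and 0.15, and C6F(L) at 0.09 and 0.12. No test was run on the positions, and C6F5UE-C6F(L)V share a count table with pHeps while the other induced groups do not.

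**Figure D4:**
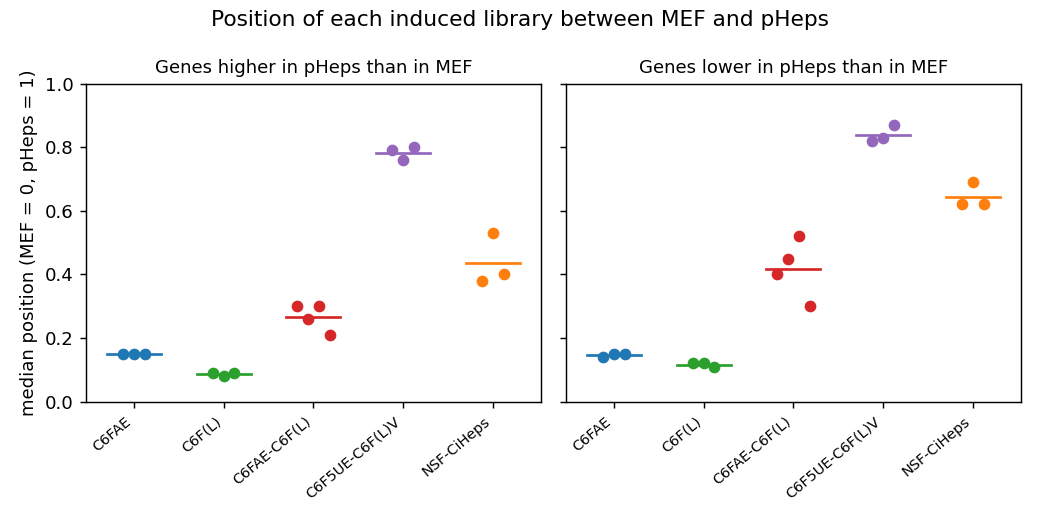
Median position of each induced library between MEF (0) and pHeps (1) on the y axis, by group on the x axis, over genes higher (left) and lower (right) in pHeps, with 1 point per library and a line at the group mean. C6F5UE-C6F(L)V lie from 0.76 to 0.80 and from 0.82 to 0.87, and C6FAE-C6F(L) from 0.21 to 0.30 and from 0.30 to 0.52.

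C6F5UE-C6F(L)V against C6FAE-C6F(L) set the protocols side by side. Hepatocyte genes were higher with the later protocol, with Alb up by 4.73 log2 units (SE 0.65, adjusted p = 5.6e-06), apolipoprotein Apoc3 by 7.15 (SE 0.63), Cyp3a11 by 7.23 (SE 0.95), the bile acid receptor Nr1h4 by 4.82, Foxa2 by 2.42 and Hnf4a by 1.94. Keratinocyte genes were lower, with Krt5 at 0.432 CPM (-13.90, and -14.79 without C6F5UE-C6F(L)V replicate 2) and its regulator Trp63 at 0 counts against 145 CPM, at least 1541-fold lower. Cell cycle genes were lower, such as Mki67 (-3.85) and Cenpf (-3.92), and so were Nkd1 (-4.87), Lox (-7.27), Thy1 (-3.10) and Col1a1 (-5.43, and -4.23 without C6FAE-C6F(L) replicate 4). Cdh1 (-1.28) and Epcam (-2.20) were lower, while Afp (-0.24, adjusted p = 0.759), Sall4 (adjusted p = 0.299) and Sox17 (-0.96, adjusted p = 0.0972) did not pass, though Sox17 did without C6FAE-C6F(L) replicate 3 (-1.19, adjusted p = 0.0411). All 24 secreted proteins were higher (camera adjusted p = 1.2e-08, and adjusted p = 0.275 with an estimated correlation), 19 of 23 enzymes were higher and 1 lower (camera adjusted p = 1.3e-06, and adjusted p = 0.254 with an estimated correlation), 18 of 23 drug metabolism genes were higher (camera adjusted p = 1.1e-05, and adjusted p = 0.275 with an estimated correlation) and 11 of 16 transcription factors were higher and 2 lower (camera adjusted p = 0.00378, and adjusted p = 0.337 with an estimated correlation). Of 10 keratinocyte genes 9 were lower and 1 higher (camera adjusted p = 2.2e-04, and adjusted p = 0.275 with an estimated correlation). Of 26 fibroblast genes 21 (camera adjusted p = 1.7e-05, and adjusted p = 0.46 with an estimated correlation), of 25 cell cycle genes 18 (camera adjusted p = 1.3e-06, and adjusted p = 0.289 with an estimated correlation) and of 17 Wnt targets 13 were lower (camera adjusted p = 3.9e-04, and adjusted p = 0.137 with an estimated correlation). Over all genes 3660 were higher and 4233 lower, and without C6FAE-C6F(L) replicate 4 there were 3772 and 4034. There were 2 enzymes lower when adjusted over the list alone, and the other list counts were the same. Xist was at 1367 CPM in C6F5UE-C6F(L)V and 480 ± 260 CPM in C6FAE-C6F(L), and the Y-linked Ddx3y at 4.51 and 45.7 ± 33 CPM. The sexes were thus not balanced. The protocols also differ in several compounds and in the count table, so that no single difference can be told apart.

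NSF-CiHeps against C6F5UE-C6F(L)V compared skin with embryonic fibroblasts as the start of the same protocol. Hepatocyte genes were lower from skin fibroblasts, with Alb at 305 ± 218 CPM (log2 fold change -4.98, SE 0.74, adjusted p = 2.7e-05), antithrombin, Serpinc1, at -6.10, the bile acid conjugating enzyme Baat at -7.28, the bile salt pump Abcb11 at -4.76, the fatty acid regulator Ppara at -4.66 and haptoglobin, Hp, at -4.96. Hnf4a was at 145 ± 34.6 against 172 CPM and did not pass (-0.24, adjusted p = 0.552). Cell cycle genes were higher, such as Mki67 (3.62), Cenpf (3.72) and Top2a (2.92), with Rrm2 lower (-1.12, and not called at -0.99 without C6F5UE-C6F(L)V replicate 2 or at -0.98 without NSF-CiHeps replicate 3). The Wnt target and stem cell receptor Lgr5 (4.86, and 5.88 without C6F5UE-C6F(L)V replicate 2), the intestinal regulator Cdx2 (5.43, and 4.54 without NSF-CiHeps replicate 3), the intestinal cadherin Cdh17 (5.14), the chloride channel Cftr (8.67) and the retinol transporter Stra6 (7.21) were higher. Interferon genes were lower, such as Isg15 (-5.05) and Ifi44 (-5.55). Afp was lower (-2.47, adjusted p = 0.008, and -4.46 without NSF-CiHeps replicate 2), a call lost with only the compared groups in the fit (adjusted p = 0.0791), and Epcam was higher (1.60).

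By list, 22 of 24 secreted proteins were lower in NSF-CiHeps (camera adjusted p = 7.8e-10, and adjusted p = 0.319 with an estimated correlation), as were 20 of 23 metabolic enzymes (camera adjusted p = 3.9e-09, and adjusted p = 0.0958 with an estimated correlation), 12 of 23 drug metabolism genes (camera adjusted p = 0.00183, and adjusted p = 0.345 with an estimated correlation) and 12 of 15 interferon genes (camera adjusted p = 1.1e-05, and adjusted p = 0.319 with an estimated correlation). Of 16 transcription factors 9 were lower and 1 higher (camera adjusted p = 0.0372, and adjusted p = 0.54 with an estimated correlation), and 8 of 14 acute phase genes were lower (camera adjusted p = 0.00139, and adjusted p = 0.319 with an estimated correlation). Of 25 cell cycle genes 20 were higher and 1 lower (camera adjusted p = 5.8e-12, and adjusted p = 0.194 with an estimated correlation), and of 17 Wnt targets 11 were higher (camera adjusted p = 1.1e-05). Of 9 intestine and stomach genes 5 were higher and 1 lower (camera adjusted p = 0.163). Cdh1 (0.38, adjusted p = 0.374), Col1a1 (-1.02, adjusted p = 0.288), Thy1 (-1.70, adjusted p = 0.0504), Sox17 (0.96, adjusted p = 0.134) and Sall4 (adjusted p = 0.054) did not pass. Without NSF-CiHeps replicate 2, Col1a1 was called at -2.59 (adjusted p = 0.0174) and Thy1 at -4.34 (adjusted p = 2.5e-04). Without NSF-CiHeps replicate 3, Sox17 was called at 1.46 (adjusted p = 0.00936), without C6F5UE-C6F(L)V replicate 2, Sall4 as lower, by at least 7.51-fold with 0 counts in NSF-CiHeps (adjusted p = 0.0273), and without NSF-CiHeps replicate 1, Cdh1 was at -0.06 (adjusted p = 0.932). Over all genes 2280 were higher and 3008 lower. Adjusted over the list alone, 12 Wnt targets and 6 intestine genes were higher, 11 acute phase and 2 intestine genes were lower, and the other list counts were the same. Mitochondrial genes took 2.49 ± 0.18% of counts in NSF-CiHeps and 0.64 ± 0.27% in C6F5UE-C6F(L)V. Xist was at 281 ± 203 CPM in NSF-CiHeps and 1367 CPM in C6F5UE-C6F(L)V, and the Y-linked Ddx3y at 33.2 and 4.51 CPM, so the sexes were not balanced. The groups also come from different count tables and starting cells, and these differences cannot be told apart.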

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

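Of the tests in this part, those of library scaling, of keratinocytes in the fibroblast culture, of their outgrowth, of depth and of other splits of the libraries were chosen only after the result was seen. Macrophage genes were present in MEF and most of them were lower in C6FAE, C6F(L) and C6FAE-C6F(L). Of a further list of 34 macrophage genes that shares none with the first, 33 were at 1 CPM or more in MEF, and 32 of these (96.97%) were lower in C6FAE, C6F(L) and C6FAE-C6F(L). The most abundant were Mrc1 (610 CPM in MEF and 0.966 in C6FAE), Mpeg1 (423 and 0.746) and Lcp1 (237 and 1.49), the exception was Cd14, at 105.1 CPM in MEF and 172 in C6FAE-C6F(L), and in C6F5UE-C6F(L)V Cybb was at 98.7 CPM against 74.8 in MEF. Library scaling is argued against by the size of the fall, since library size only moved the median of all genes at most from 0.02 to 0.12, in C6FAE. With it the highest of the 3 median log2 fold changes of the first list was -9.45. That value could hardly have come out otherwise and is no separate test. A candidate explanation is macrophages in the fibroblast culture that were lost during induction, a hypothesis found and tested on the same data, and no sort or gate that would remove them is named in the labels.

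Keratinocyte genes in C6FAE-C6F(L) summed to 13875 ± 3228 CPM over a list of 10 genes, of which Krt5 took 6827 CPM. The sum in MEF was 39.2 ± 0.622 CPM, 0.2824% of it, so the rise itself leaves no room for keratinocytes at that share in the fibroblast culture, and this value is no separate test. The sums were 65.9 CPM in C6FAE, 173 ± 139.9 in C6F(L), 208 in C6F5UE-C6F(L)V, 252.5 in NSF-CiHeps and 213 in pHeps. The listed gene Perp alone took 33.65 CPM in MEF and 195.2 CPM in pHeps, where Krt5 was at 0 and 1.235 CPM. Most of the sum in MEF and in pHeps was thus Perp. Outgrowth of a few keratinocytes from below the detection floor stays open, since a rise of at least 78596.0-fold for Krt5 from 0 counts may come from a small number of cells or from a change of state, and the tables hold no value that separates them. An effect of the sequential treatment, which the design names, is also open and was not tested further.

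C6FAE-C6F(L) replicate 4 lay far from the other 3 of its group. Its mean correlation with them was 0.945 against 0.963 for the others, and its Col1a1 level of 1172.2 CPM was far above the others (189 ± 71.8 CPM). Depth is argued against, since its total of 10.95 M counts lay within the group's 10.83 M to 11.41 M, and so are a few abundant genes or ribosomal protein genes, since without these its mean correlation was 0.9406 against 0.9583 to 0.9616. A larger share of unconverted fibroblasts could account for 25 of 26 fibroblast genes being highest and 19 of 25 epithelial genes lowest in it (6.5 and 6.25 by chance), but at most 70.00% of the fibroblast genes implied a share within 2-fold of their median of 14.42%, with C6F(L) as the source, so this stays open. The other lists did not all show such a loss, with 3 of 19 secreted proteins (4.75 by chance), 3 of 10 keratinocyte genes (2.5) and 5 of 8 intestine and stomach genes (2) lowest in it and 4 secreted proteins highest, and no other biological explanation was tested. The numbers by chance hold for a library not chosen for lying apart. Genes of a list also move together, with an estimated correlation of 0.88 for fibroblast and 0.24 for epithelial genes, so the excess is no test.

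One further value stood far from its group, Nkd1 at 5.757 CPM in C6FAE-C6F(L) replicate 3 against 14.4 ± 0.329 CPM in the other 3. With Dixon's test, 3 of 58 values were above the critical ratio, and chance gives about 1 in 20.

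The change to C6F(L) differed between C6FAE cells and MEF in the test of the interaction, for 2677 genes with a positive and 2782 with a negative difference. C6FAE cells started with the compounds and MEF without them, so these differences do not by themselves show another action of C6F(L). In log2 units it was -15.00 for Sp5, -10.12 for Notum, -14.96 for Cyp26a1, -2.04 for Cdh1, -4.16 for Epcam, -2.54 for Col1a1, -4.47 for Thy1, -9.46 for Sox17, -4.59 for Fbln1, -5.90 for Twist1 and -3.69 for Nr4a1. It was 11.38 for Oas1a, 9.37 for Isg15, 2.34 for Sc5d and 10.96 for Afp. Cdh1 and Epcam started near 0 in MEF and gained more CPM after C6FAE, so their negative differences hold in log2 units only. The values for Sp5, Sox17 and Afp were fitted with groups at 0, 3 and 1 to 2 counts, depend on the prior count and are no bounds. From count shares Sp5 was at -12.05 or lower, Sox17 at -9.63 (-11.91 to -8.08) and Afp at 11.53 (6.34 to 20.20). Positive differences were called for 8 secreted proteins, 7 drug metabolism genes, 14 interferon, 16 cholesterol and 5 stress genes. They were called for 6 macrophage genes too, which were at 7.78 CPM (Cd68) or less in C6FAE, so that the median difference restates their loss from MEF and is no evidence of another effect of C6F(L). They were also called for 4 of 10 keratinocyte genes (camera adjusted p = 0.033, and adjusted p = 0.576 with an estimated correlation), a count that was 2 without MEF replicate 1, for 2 of 6 adipocyte genes (camera adjusted p = 0.0232, and adjusted p = 0.336 with an estimated correlation) and for 3 of 8 intestine and stomach genes (camera adjusted p = 0.00837, and adjusted p = 0.177 with an estimated correlation). Negative differences were called for 15 fibroblast, 13 Wnt, 11 cAMP, 7 retinoic acid and 6 muscle genes. Adjusted over the list alone, the counts were the same except for 7 muscle genes.

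Other splits of the same libraries gave fewer genes than the real one in each comparison of groups of at least 3. C6FAE-C6F(L) was compared with MEF (6190 genes, 5004 in the highest of the other splits), C6FAE (5573 and 4074), C6F(L) (5294 and 4226) and C6F5UE-C6F(L)V (7893 and 4545). In each, 1 of 35 splits, the real one, gave as many, a share under 0.05 and the lowest that 35 splits can give. This addresses only how these libraries were assigned to groups. It does not cover differences between cultures, since the labels do not say that libraries of a group are independent. The interaction gave 5459 genes and 1058 in the highest other of 100 drawn splits. Those splits shuffled libraries over all 4 groups and so mixed the differences between groups, which cannot exclude chance for the interaction itself. In the 4 comparisons with 35 splits the highest other split placed C6FAE-C6F(L) replicate 4 with the other group's 3 libraries. For C6FAE and C6F(L) against MEF (5021 and 3802 genes, with 0 in the highest other split by edgeR) and NSF-CiHeps against C6F5UE-C6F(L)V (5288 and 3), 10 splits are too few for a share under 0.05.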

How the results depend on the processing

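The tests on genes at 1 CPM or more in each of the 4 groups and on positions with a library of the described group left out were chosen only after seeing the data, and so were the count ratios and bounds with a library left out. The first gave 1916 genes higher and 1771 lower in the interaction (2677 and 2782 in the test as chosen), by construction from fewer genes, and 67.54% of the calls were kept. Of the alternatives for named genes, 13690 kept direction and side of the threshold, 371 lost the call, 21 gained it and 2 reversed. Col1a1 lost its call with the DESeq2 test, which set no adjusted p for it, in C6FAE, C6FAE-C6F(L) and pHeps against MEF. The same held for Col1a1 in C6FAE-C6F(L) against C6FAE and C6F(L), in C6F5UE-C6F(L)V against C6FAE-C6F(L) and in the interaction. The reversed ones were Afp in C6FAE against MEF, at 0.29 without MEF replicate 2 and from -3.49 to 0.29 over the libraries left out, and Cdh1 in NSF-CiHeps against C6F5UE-C6F(L)V, at -0.06 without NSF-CiHeps replicate 1 and from -0.06 to 0.81, neither of them called and Afp at 4 counts or fewer in both groups. Positions moved with the prior count (0.5 and then 5) to 0.17 and 0.13 for C6FAE over genes higher in pHeps, 0.14 and 0.16 over genes lower, and for C6F(L) to 0.10 and 0.08 and to 0.11 and 0.13. With library size only they were 0.19 and 0.11 for C6FAE, 0.08 and 0.13 for C6F(L), 0.84 and 0.79 for C6F5UE-C6F(L)V and 0.60 over genes lower for NSF-CiHeps. The causes were not tested. Leaving out each library in turn gave 2411 to 2470 genes higher for C6FAE against MEF, 1554 to 1662 for C6F(L), 2708 to 3135 for C6FAE-C6F(L) against MEF, 2489 to 2690 for the interaction, 2614 to 2803 against pHeps and 2078 to 2308 for NSF-CiHeps. With the replicate number as a block, C6FAE-C6F(L) against MEF gave 3166 and 3540 genes. The numbers do not pair the libraries, since the residuals of 20 same-number pairs correlated at -0.03 to 0.02. With an estimated correlation, 117 of the 131 list tests called with the preset correlation lost their call. In the simulation 3-fold changes were recovered for 52.53% to 73.68% of genes, so that changes of that size can be missed.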

Other observations

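Sex-linked genes differed between the groups, which no comparison was set up to test, so they are given as values, chosen after they were seen. Xist, the RNA of X inactivation, was at 416 CPM in MEF, 511 in C6FAE, 751 in C6F(L) and 480 ± 260 in C6FAE-C6F(L) (191 to 766 over 4 libraries). It was at 1367 ± 66.5 CPM in C6F5UE-C6F(L)V, 281 ± 203 in NSF-CiHeps (53.9 to 445) and 0.0472 in pHeps. The Y-linked gene Ddx3y was at 50.6 CPM in MEF, 38.6 in C6FAE, 34.5 in C6F(L), 45.7 ± 33 in C6FAE-C6F(L), 4.51 in C6F5UE-C6F(L)V, 33.2 in NSF-CiHeps and 60.3 in pHeps. The Y-linked Eif2s3y was at 19.6, 25.9, 25.4, 49 ± 39.5, 10.8, 47.8 and 128 CPM in the same order of groups. Both kinds of gene were present in every group except pHeps, which held 1 count of Xist, so the sexes were not balanced between pHeps and the other groups. C6F5UE-C6F(L)V had the most Xist and the least of both Y-linked genes, so the sexes were not balanced between them and the other groups either.

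Other gene groups that the comparisons did not describe moved too. Against C6FAE, of 17 cholesterol synthesis genes 8 rose in C6FAE-C6F(L) (camera adjusted p = 8.4e-04, and adjusted p = 0.351 with an estimated correlation), 9 of 13 glucocorticoid genes rose and 1 fell (camera adjusted p = 6.3e-04, and adjusted p = 0.206 with an estimated correlation), and all 8 intestine and stomach genes rose (camera adjusted p = 0.0012, and adjusted p = 0.158 with an estimated correlation). C6F5UE-C6F(L)V held 10 of 15 interferon genes higher than C6FAE-C6F(L) (camera adjusted p = 0.00843, and adjusted p = 0.462 with an estimated correlation) and 10 of 17 cholesterol genes lower with 1 higher (camera adjusted p = 0.00499, and adjusted p = 0.462 with an estimated correlation). Adjusted over the list alone, these counts were the same.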
